A study of Mus musculus with 14 samples.

How the data were processed

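Single epithelial cells of the mouse proximal jejunum were sorted by the Lgr5-eGFP reporter and profiled with a droplet method that counts UMIs at transcript 3′ ends. The deposited matrices hold raw counts of UMIs per gene and cell barcode, without normalization by the authors, for 27998 genes. The submitters' processing notes name Cell Ranger and the mm10 genome without versions. The barcodes had been filtered to cells before deposition, since none of the 13247 barcodes lay under 500 UMIs. Gene positions came from a GRCm38 annotation that may differ from the one used by the submitters: 27645 of 27998 identifiers matched it, 353 did not, and 26501 had the same symbol. The 14 libraries were assigned to 7 groups of 2 by their labels. The series text calls the 2 libraries of a group technical replicates, whereas the extract protocol calls them biological, so p-values may measure only technical spread. The chi-square statistic between the 2 libraries of a group over its degrees of freedom ran from 1.307 to 3.191, for genes with at least 20 counts.

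Barcodes with at least 500 genes, at least 1000 UMIs and at most 20% of UMIs from mitochondrial genes were kept, which removed 5 and left 13242. Depth per library is given with the results, and median UMIs per cell ran from 5069 to 8908. Counts were scaled to 10000 per cell and log-transformed with 1 added. After leaving out 49 stem and Wnt genes, mitochondrial genes and ribosomal protein genes, 2000 highly variable genes gave 30 principal components, 15 nearest neighbours and Leiden clusters at resolution 1 with seed 1, 16 in number, without batch integration. Clusters were named after the fixed marker list with the highest score, or after a list with more members among the cluster's top 10 genes. A name required a score of at least 0.5 and at least 3 raised markers. Clusters of low depth for their libraries stayed unnamed if none of these markers was among the top 10 genes. This left cluster 15 unnamed, with 37 cells and a stem marker score of 1.8419. The naming score rule, and the score of 0.5 that divides cycling clusters into high and low stem markers, were set after the data were seen. Doublets were simulated at 2 per cell, cells with at least 90% simulated neighbours were marked, and the 470 marked cells (3.549%) stayed in except in an alternative. For shares of cells with a UMI, cells were thinned to 3600 UMIs, which left out 1320 shallower cells. Intervals are exact binomial at 95%, floors stand for 3 counts, and both cover counting error only.

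UMI counts were summed per library over all kept cells, and over ISC-like cells where a library held at least 20. Sums were tested with edgeR quasi-likelihood fits after TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment and adjusted p under 0.05 as the threshold. One fit held the 12 eGFP-positive libraries, and another held all 14 for the comparison of eGFP-positive with eGFP-negative control cells. Cell numbers per class were tested with edgeR with kept cells as library size. Gene lists, fixed before the data were examined, were tested with camera at a preset inter-gene correlation, and their members were also adjusted over the list alone. No pairing was used since the labels do not say what the replicate numbers share.

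Genes to name were chosen by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls per comparison (6 and 6 in ISC-like cells) among genes with adjusted p under 0.05, a mean of at least 20 CPM, a log2 change of at least 0.58 and both libraries of a group above both of the other. Predicted gene models, mitochondrial genes and ribosomal protein genes were left out. The rule added up to 4 members per gene list with the smallest adjusted p, and Lgr5, Ascl2, Axin2, Olfm4 and Mki67 in every comparison. The genes printed are examples from those the rule names, picked for their known function after their values were seen. Alternatives covered normalization, count filter, test, minimum fold, fit, cell filter, doublets, immune-like cells, clustering, replicate number and single libraries left out. The pipeline was tested on simulated data. In a comparison with the depth of Rspo1 against control, changes of 1.25, 1.5, 2 and 4 fold were called for 32%, 68%, 80% and 94% of genes, with 13 false among 150 calls. Other comparisons differed, with 8%, 40%, 56% and 88% for LGR5 ECD against Fzd8 CRD and 38%, 64%, 86% and 98% for RSPO2 against Rspo1. For Rspo1 within ISC-like cells the shares were 12%, 42%, 80% and 94%. An ISC-like share at 0.8 of its size was called in 24 of 50 draws. Comparisons within ISC-like cells of the loss-of-function groups were left out for lack of cells. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.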

Results

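RNA was measured in single epithelial cells of the mouse proximal jejunum by droplet capture and counting of unique molecular identifiers (UMIs) at transcript 3′ ends. The mice carried an eGFP and CreER reporter in Lgr5, the gene of an R-spondin receptor that marks crypt base stem cells, and had received an intravenous adenovirus encoding a secreted protein. The 14 libraries fell into 7 groups of 2. The control virus encoded Fc, an antibody fragment, and gave 1 group of eGFP-positive and 1 group of eGFP-negative cells, whereas the other 5 groups held eGFP-positive cells. Fzd8 CRD, the Wnt-binding domain of a Frizzled receptor, was labelled a Wnt loss of function, and LGR5 ECD, the R-spondin-binding part of LGR5, an R-spondin loss of function. Rspo1 and RSPO2, both R-spondins, were labelled gain of function, as was scFv-DKK1c, an engineered Wnt agonist. The eGFP-positive control libraries held 712 and 1030 cells with 5533548 and 7628999 UMIs, and the eGFP-negative control libraries 650 and 1325 cells with 3332540 and 7024436 UMIs. Loss of function was represented by 390 and 583 cells with 2755984 and 4346753 UMIs for Fzd8 CRD, and by 589 and 750 cells with 4455734 and 5927176 UMIs for LGR5 ECD. For gain of function there were 1284 and 1412 cells with 10375260 and 10627510 UMIs with Rspo1, 1345 and 1200 cells with 12225402 and 10055156 UMIs with RSPO2, and 1092 and 880 cells with 8391017 and 6818440 UMIs with scFv-DKK1c.

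Levels are UMI counts scaled to library totals (CPM) over all kept cells of a library, given as mean ± SD over the 2 libraries of a group. Fitted changes are on the log2 scale with their standard error, and adjusted p-values are from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment. The series text calls the 2 libraries of a group technical replicates and the extract protocol calls them biological, so the p-values may measure technical spread only. All 5 treated groups were compared with the same 2 eGFP-positive control libraries, so those comparisons share their errors. The genes followed in every comparison were Lgr5 (ENSMUSG00000020140, GRCm38 chromosome 10, 115450311 to 115587780, minus strand), Ascl2 (ENSMUSG00000009248, chromosome 7, 142966829 to 142969264, minus strand), Axin2 (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783, plus strand), Olfm4 (ENSMUSG00000022026, chromosome 14, 79984081 to 80023139, plus strand) and Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361, minus strand). Each is a protein-coding gene.

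Cells were clustered without stem and Wnt genes and then named after their markers. The intestinal stem cell-like (ISC-like) class made up 50.9% ± 3.02 of the eGFP-positive control cells (SD, n = 2) and 1.18% ± 0.361 of the eGFP-negative ones. Cycling cells with high stem markers, kept apart from this class by a threshold set after the data were seen, were 28.2% ± 0.862 and 1.64% ± 0.507. Cycling cells with low stem markers were 5.09% ± 1.15 and 2.98% ± 1.44. Every share among eGFP-positive cells depends on the sort as well as on the tissue. A share also does not show whether cells left a class or changed their RNA.

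**Figure D1:**
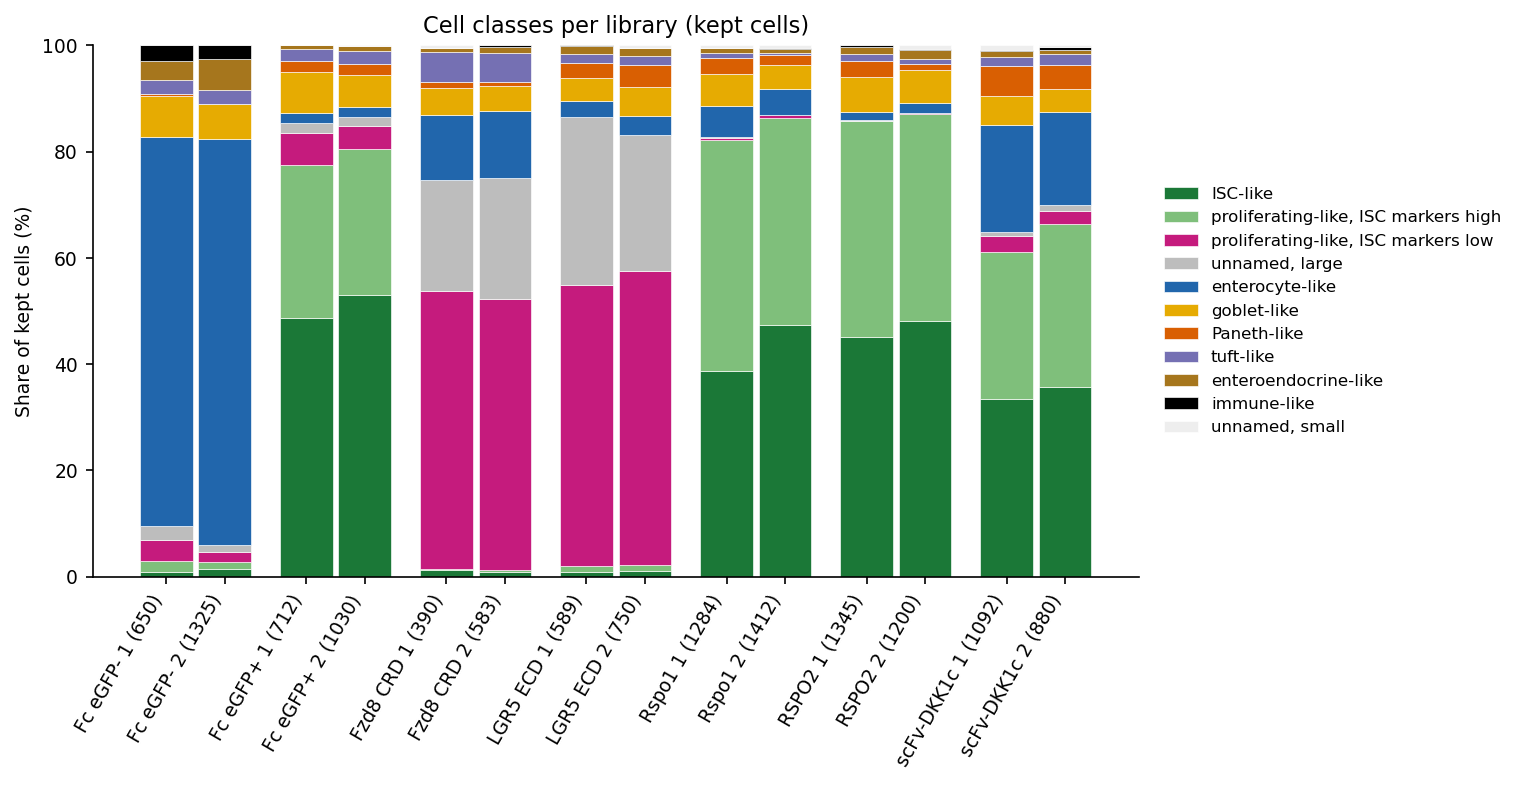
Percent of kept cells in each cell class (y axis) for the 14 libraries of the 7 groups (x axis, number of cells in brackets), as stacked bars. The mean ISC-like share falls from 50.9% in the eGFP-positive control to 1.07% with Fzd8 CRD and 0.958% with LGR5 ECD.

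The first comparison asked what the reporter gate selected in control mice. Cells sorted as eGFP-positive held more RNA of crypt base stem cell genes, and less RNA of enterocyte and antimicrobial genes, than eGFP-negative cells. Lgr5 averaged 49.03 ± 6.47 against 1.07 ± 1.096 CPM, Olfm4, a secreted glycoprotein of the crypt base, 110.0 ± 23.5 against 3.89 ± 0.867 CPM, and Ascl2, a transcription factor of stem cell identity, 219 ± 0.124 against 12.8 ± 0.763 CPM. Apoa1, an apolipoprotein of enterocytes, averaged 129 ± 1.79 against 7110.3 ± 119.8 CPM, and Reg3b, an antimicrobial lectin, 325 ± 79.4 against 3145 ± 122 CPM. Of the 33 measured genes of the stem cell signature, 33 rose and 0 fell (33 and 0 adjusted over the list alone), with camera adjusted p = 1.57e-30, or adjusted p = 0.0568 with an estimated correlation. The largest rises by the naming rule also held Rgcc, a regulator of the cell cycle, and Igfbp4, an insulin-like growth factor binding protein, at 4.05 ± 0.12 and 3.45 ± 0.09. Wnt targets had 19 rises among 21 measured members, including Axin2, a feedback inhibitor of Wnt signalling, at 2.81 ± 0.10 (camera adjusted p = 5.73e-13, or adjusted p = 0.0774 with an estimated correlation). Mki67, a marker of cycling cells, rose by 1.35 ± 0.10 and Npm1, a nucleolar chaperone, by 1.80 ± 0.05. Among S phase genes, 34 of 34 measured members rose and 0 fell (34 and 0 adjusted over the list alone), with camera adjusted p = 9.12e-14, or adjusted p = 0.0977 with an estimated correlation. Ribosome assembly genes had 15 rises and 0 falls among 16 measured members (15 and 0 adjusted over the list alone), with camera adjusted p = 3.92e-10, or adjusted p = 0.119 with an estimated correlation.

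On the other side, 0 of 20 measured enterocyte markers rose and 20 fell (0 and 20 adjusted over the list alone), with camera adjusted p = 1.16e-59. Among antimicrobial genes, 2 of 11 measured members rose and 7 fell (2 and 7 adjusted over the list alone), with camera adjusted p = 2.27e-07. Fat oxidation genes had 1 rises and 14 falls among 15 measured members (1 and 14 adjusted over the list alone), with camera adjusted p = 3.42e-06, or adjusted p = 0.0955 with an estimated correlation. Oxidative phosphorylation genes had 0 rises and 20 falls among 20 measured members (0 and 20 adjusted over the list alone), with camera adjusted p = 1e-09, or adjusted p = 0.0756 with an estimated correlation. Glycolysis genes had 1 rises and 9 falls among 12 measured members (1 and 10 adjusted over the list alone), with camera adjusted p = 4.6e-05, or adjusted p = 0.133 with an estimated correlation. Mitochondrially encoded genes had 0 rises and 10 falls among 10 measured members (0 and 10 adjusted over the list alone), with camera adjusted p = 0.00184, or adjusted p = 0.313 with an estimated correlation. The median share of mitochondrial UMIs per cell was 0.62% and 0.673% in eGFP-positive and 1.261% and 1.401% in eGFP-negative libraries. Creb3l3, a transcription factor of lipid metabolism, stood at -5.48 ± 0.12 and Ldha, a lactate dehydrogenase, at -1.65 ± 0.04. Muc2, the main secreted mucin, was lower at -3.14 ± 0.15, while the goblet-like share, 6.87% ± 1.21 against 7.09% ± 0.849, did not pass its test at -0.04 (adjusted p = 0.94). That class held different clusters: in eGFP-positive cells mostly cluster 9, 7.163% and 5.437% of cells, and in eGFP-negative cells mostly cluster 13, 6.154% and 5.66%, whose top marker genes included Muc2. Immune cell markers had 0 rises and 14 falls among 15 measured members (0 and 14 adjusted over the list alone), with camera adjusted p = 0.00786, or adjusted p = 0.469 with an estimated correlation. T cell transcripts were close to 0 in eGFP-positive cells and present in eGFP-negative cells, where Gzma, a cytotoxic granule protease, averaged 206 ± 44.2 CPM and the immune-like class was 2.78% ± 0.199. Immune-like cells were 0 of 712 and 0 of 1030 eGFP-positive control cells, which allows shares of up to 0.421% and 0.291%. Log2 ratios of shares were 5.32 (adjusted p = 2.17e-17) for ISC-like, 2.92 (adjusted p = 0.000578) for Paneth-like, -5.25 (adjusted p = 1.04e-18) for enterocyte-like and -2.50 (adjusted p = 5.45e-07) for enteroendocrine-like cells. Of 12011 genes tested, 4230 rose and 4208 fell, and 4923 passed a test against a minimum fold of 1.5.

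Does blocking Wnt ligands change the cells caught by the reporter gate? With Fzd8 CRD the stem cell genes were lower, the largest class was cycling cells with low stem markers, and genes of enterocytes, tuft cells and the interferon response were higher. Lgr5 fell to 2.52 ± 0.995 against 49.03 ± 6.47 CPM, Ascl2 to 23.3 ± 0.172 against 219 ± 0.124 CPM, Olfm4 to 7.16 ± 1.91 against 110.0 ± 23.5 CPM and Axin2 to 31.8 ± 6.04 against 142 ± 2.23 CPM. Rgcc fell furthest among rule-named genes, by 6.11 ± 0.17 on the log2 scale. Mki67 was higher, at 0.50 ± 0.08 (adjusted p = 1.5e-05). The ISC-like share was 1.07% ± 0.3 and that of cycling cells with high stem markers 0.3% ± 0.062, whereas cycling cells with low stem markers reached 51.7% ± 0.844. Their log2 ratios to control were -5.61 (adjusted p = 5.55e-13), -6.45 (adjusted p = 9.69e-13) and 3.38 (adjusted p = 5.55e-13). A further cluster of 683 cells without a marker-based name was 21.7% ± 1.32 against 1.81% ± 0.223. Tuft-like cells were 5.57% ± 0.107 against 2.34% ± 0.127, a log2 ratio of 1.23 (adjusted p = 0.000494), and enterocyte-like cells 12.5% ± 0.272 against 1.95% ± 0.017. Loss of cells with high stem markers alone would raise the shares of all other classes by the same factor. The fitted folds were 10.4 for cycling cells with low stem markers, 12.18 for the unnamed cluster, 6.384 for enterocyte-like and 2.352 for tuft-like cells. For goblet-like cells the fold was 0.7175, which did not pass its test (adjusted p = 0.0954). These unequal folds argue against such a loss as the only source of the rises, and a gain in cell number was not tested.

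Of the 21 measured Wnt targets, 1 rose and 18 fell (1 and 18 adjusted over the list alone), with camera adjusted p = 3.95e-27. Sox4, a transcription factor, and Sp5, a direct target of beta-catenin, fell by 1.93 ± 0.08 and 2.61 ± 0.14. Of the 26 measured interferon response genes, 21 rose and 1 fell (21 and 1 adjusted over the list alone), with camera adjusted p = 3.64e-32. Isg15, a ubiquitin-like protein, averaged 264 ± 10.7 against 32.02 ± 0.977 CPM, and Irf7, an interferon regulatory factor, 241 ± 5.72 against 77.4 ± 1.91 CPM. Immune cell markers had 8 rises and 0 falls among 12 measured members (10 and 0 adjusted over the list alone), with camera adjusted p = 0.0115, or adjusted p = 0.458 with an estimated correlation. Immune-like cells were 0 of 390 and 2 of 583 with Fzd8 CRD and 0 in both control libraries, so these rises may rest on few cells of 1 library. Of the 16 measured genes of the unfolded protein response, 12 rose and 0 fell (13 and 0 adjusted over the list alone), with camera adjusted p = 2.45e-15. Manf, a protein of the endoplasmic reticulum, stood at 1.37 ± 0.05. Cholesterol synthesis rose nearly throughout, where 17 of 18 measured genes rose and 0 fell (18 and 0 adjusted over the list alone), with camera adjusted p = 2.58e-11. Fdps, which makes farnesyl diphosphate, averaged 160.0 ± 1.09 against 77.5 ± 1.56 CPM. Of the 11 measured antimicrobial genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone), with camera adjusted p = 1.06e-11. Of the 12 measured tuft markers, 12 rose and 0 fell (12 and 0 adjusted over the list alone), with camera adjusted p = 7.24e-10, or adjusted p = 0.11 with an estimated correlation. Among Paneth markers, 0 of 14 measured members rose and 13 fell (0 and 13 adjusted over the list alone), with camera adjusted p = 3.3e-06, or adjusted p = 0.257 with an estimated correlation. Lyz1, a lysozyme, averaged 164 ± 16.4 against 341 ± 52.6 CPM. Among immediate early genes, 1 of 15 measured members rose and 10 fell (1 and 10 adjusted over the list alone), with camera adjusted p = 0.000138, or adjusted p = 0.173 with an estimated correlation. Jun and Fos, members of the AP-1 complex, stood at -1.63 ± 0.10 and -1.67 ± 0.16. Of 11754 genes tested, 2406 rose and 2228 fell, and 1072 passed a test against a minimum fold of 1.5. Genes within ISC-like cells were not tested for the loss-of-function groups, which held 5 to 8 such cells per library.

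Capture of R-spondins by LGR5 ECD addressed the need of the same cells for R-spondin. Stem cell genes fell and cycling cells with low stem markers dominated, Paneth cell genes rose, and interferon response genes were higher. Lgr5 averaged 5.11 ± 0.882 against 49.03 ± 6.47 CPM, Ascl2 31.8 ± 4.94 against 219 ± 0.124 CPM, Olfm4 6.43 ± 2.12 against 110.0 ± 23.5 CPM and Axin2 60.02 ± 3.63 against 142 ± 2.23 CPM. The ISC-like share was 0.958% ± 0.154, a log2 ratio of -5.70 (adjusted p = 2.17e-13), with 1.19% ± 0.008 in cycling cells with high stem markers. Cycling cells with low stem markers were 54.1% ± 1.79 and the unnamed cluster 28.7% ± 4.35, at log2 ratios of 3.45 (adjusted p = 2.2e-13) and 3.99 (adjusted p = 1.27e-12). Genes of the stem cell signature had 1 rises and 32 falls among 33 measured members (1 and 32 adjusted over the list alone), with camera adjusted p = 1.52e-68. Phlda1, a crypt base gene of the signature, and Id2, an inhibitor of DNA binding, stood at -2.95 ± 0.11 and -2.36 ± 0.12. Among Wnt targets, 1 of 21 measured members rose and 16 fell (1 and 17 adjusted over the list alone), with camera adjusted p = 3.71e-32. Mki67 was higher, at 0.43 ± 0.07 (adjusted p = 6.77e-05).

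Of the 14 measured Paneth markers, 13 rose and 0 fell (13 and 0 adjusted over the list alone), with camera adjusted p = 3.91e-06, or adjusted p = 0.258 with an estimated correlation. Lyz1 averaged 691 ± 72.6 against 341 ± 52.6 CPM and Defa17, an alpha-defensin, 655 ± 3.61 against 343 ± 37.4 CPM, while the Paneth-like share, 3.44% ± 0.788 against 2.002% ± 0.052, did not pass its test at 0.80 (adjusted p = 0.106). Both CPM and shares have a fixed total, so these Paneth values can rise through the loss of cells with high stem markers, without a gain in Paneth-like cells. Among interferon response genes, 21 of 26 measured members rose and 1 fell (21 and 1 adjusted over the list alone), with camera adjusted p = 1.19e-23. Ly6a, a surface antigen induced by interferon, averaged 87.4 ± 7.44 against 5.19 ± 2.48 CPM and Isg15 163 ± 4.16 against 32.02 ± 0.977 CPM. Of the 7 measured MHC class II genes, 0 rose and 6 fell (0 and 6 adjusted over the list alone), with camera adjusted p = 3e-07. H2-Eb1, an antigen-presenting chain, averaged 194 ± 12.2 against 345 ± 14.6 CPM. Of the 18 measured cholesterol synthesis genes, 16 rose and 0 fell (16 and 0 adjusted over the list alone), with camera adjusted p = 1.85e-08, or adjusted p = 0.0509 with an estimated correlation. Of the 16 measured genes of the unfolded protein response, 12 rose and 1 fell (12 and 1 adjusted over the list alone), with camera adjusted p = 2.24e-08. Among tuft markers, 0 of 12 measured members rose and 0 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.337. Gt(ROSA)26Sor, a non-coding gene at a locus commonly used for transgenes, showed the largest rule-named rise, 46.4 ± 0.44 against 0.795 ± 0.358 CPM. It also averaged 20.6, 17.2, 16.2 and 18.4 CPM with Fzd8 CRD, Rspo1, RSPO2 and scFv-DKK1c, against 0.36 in eGFP-negative control cells. Its rise was thus not particular to LGR5 ECD, and a difference between control and treated animals cannot be told apart from the encoded proteins. Acp1, an acid phosphatase, fell to 18.03 ± 3.604 against 158 ± 1.64 CPM. The test covered 11754 genes, of which 1972 rose and 1869 fell. DESeq2 called 2532 genes, and 495 passed a test against a minimum fold of 1.5.

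The losses of function were also compared directly, which asks whether blocking R-spondin and blocking Wnt leave the same cells. With LGR5 ECD, Paneth cell genes were higher and tuft and enterocyte genes lower than with Fzd8 CRD, and Axin2 kept more of its level. Axin2 averaged 60.02 ± 3.63 against 31.8 ± 6.04 CPM and Ascl2 31.8 ± 4.94 against 23.3 ± 0.172 CPM. Lgr5, 5.11 ± 0.882 against 2.52 ± 0.995 CPM, and Olfm4, 6.43 ± 2.12 against 7.16 ± 1.91 CPM, did not pass the test, at adjusted p = 0.105 and 0.871. Among Paneth markers, 14 of 14 measured members rose and 0 fell (14 and 0 adjusted over the list alone), with camera adjusted p = 4.11e-58. Clps, a pancreatic-type colipase, and Mptx2, a pentraxin, averaged 359 ± 6.11 against 81.8 ± 2.35 CPM and 150.3 ± 1.48 against 16.7 ± 10.8 CPM. Among tuft markers, 0 of 12 measured members rose and 12 fell (0 and 12 adjusted over the list alone), with camera adjusted p = 2.02e-39. Alox5ap, an activator of leukotriene synthesis, averaged 24.04 ± 1.31 against 121 ± 4.37 CPM. Among enterocyte markers, 0 of 20 measured members rose and 17 fell (0 and 18 adjusted over the list alone), with camera adjusted p = 2.37e-63. Apoa4 averaged 104 ± 14.4 against 407 ± 16.9 CPM. Log2 ratios of class shares were 1.91 (adjusted p = 0.0188) for Paneth-like, -1.68 (adjusted p = 0.000224) for tuft-like, -1.93 (adjusted p = 1.4e-06) for enterocyte-like and -0.08 (adjusted p = 0.949) for ISC-like cells. The ISC-like ratio turned to 0.69 (adjusted p = 0.274) with the cycling clusters of high stem markers included, which was tried after the data were seen, to 0.18 (adjusted p = 0.814) without library 1 of Fzd8 CRD and to 0.052 (adjusted p = 0.94) without library 1 of LGR5 ECD. Of the 26 measured interferon response genes, 1 rose and 12 fell (1 and 15 adjusted over the list alone), with camera adjusted p = 4.47e-11. Immune cell markers had 1 rises and 3 falls among 12 measured members (1 and 3 adjusted over the list alone), with camera adjusted p = 0.0355, or adjusted p = 0.532 with an estimated correlation. The immune-like class held only 0 to 2 cells per library in these groups. Fzd5, a Frizzled receptor, was higher with LGR5 ECD at 1.39 ± 0.10. Of 11754 genes tested, 359 rose and 703 fell. The count was 668 with DESeq2, 232 against a minimum fold of 1.5, 548 without library 2 of Fzd8 CRD and 692 without library 1 of LGR5 ECD.

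**Figure D2:**
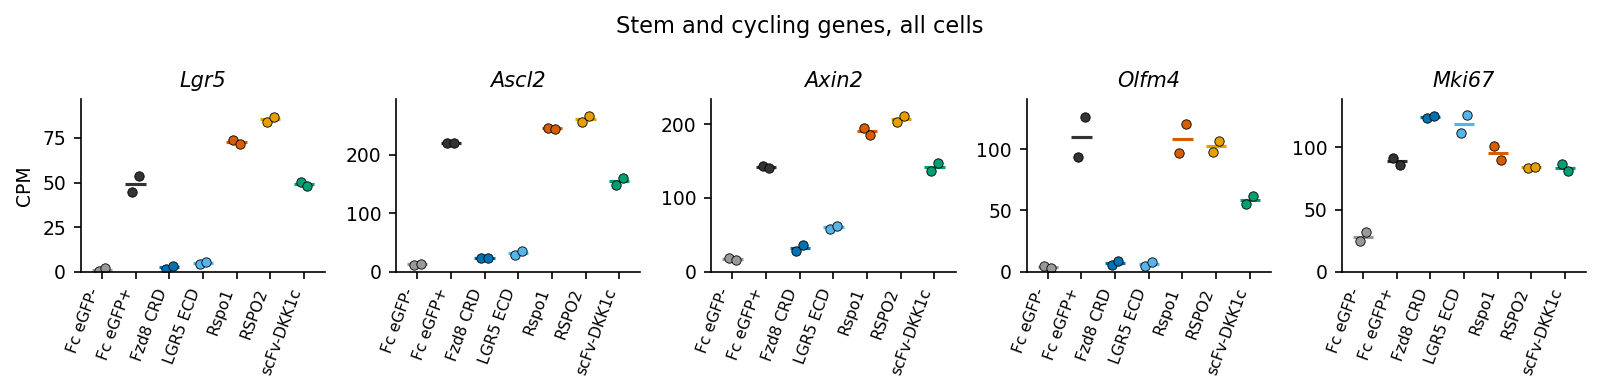
CPM over all kept cells (y axis) of Lgr5, Ascl2, Axin2, Olfm4 and Mki67 in the 7 groups (x axis), with a dot per library and a line at the mean of the 2 libraries. Lgr5 averages 2.52 CPM with Fzd8 CRD and 5.11 with LGR5 ECD against 49.0 in the eGFP-positive control, and 72.7 with Rspo1 and 85.4 with RSPO2.

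Rspo1 gain of function asked how added R-spondin changes the reporter-positive cells. Wnt target, MHC class II, interferon response and enterocyte genes rose, part of the stem genes rose, and goblet, tuft and cholesterol synthesis genes fell. Lgr5 averaged 72.7 ± 1.64 against 49.03 ± 6.47 CPM and Axin2 190.0 ± 6.93 against 142 ± 2.23 CPM, changes of 0.55 ± 0.08 (adjusted p = 2.89e-05) and 0.41 ± 0.06 (adjusted p = 2.58e-05). Ascl2, Olfm4 and Mki67 did not pass, at 0.15, -0.04 and 0.10. Genes of the stem cell signature had 22 rises and 2 falls among 33 measured members (25 and 2 adjusted over the list alone), with camera adjusted p = 1.92e-11, or adjusted p = 0.0676 with an estimated correlation. Of the 21 measured Wnt targets, 11 rose and 1 fell (14 and 1 adjusted over the list alone), with camera adjusted p = 2.38e-08. Nkd1 (ENSMUSG00000031661, chromosome 8, 88521354 to 88594884, plus strand), a feedback inhibitor of Wnt signalling, averaged 30.9 ± 0.727 against 7.68 ± 1.92 CPM, and Tnfrsf19, a receptor found in stem cells, 47.8 ± 0.467 against 16.99 ± 2.3 CPM. Of the 7 measured MHC class II genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with camera adjusted p = 1.21e-44. H2-Aa, an antigen-presenting chain, averaged 699 ± 33.4 against 244 ± 7.23 CPM and Cd74, the invariant chain, 2592 ± 141 against 1429.8 ± 74.7 CPM. Of the 26 measured interferon response genes, 25 rose and 0 fell (25 and 0 adjusted over the list alone), with camera adjusted p = 8.05e-39. Isg15 averaged 111 ± 2.76 against 32.02 ± 0.977 CPM. Of the 14 measured fat oxidation genes, 10 rose and 2 fell (10 and 3 adjusted over the list alone), with camera adjusted p = 2.36e-14. Cholesterol synthesis genes had 0 rises and 12 falls among 18 measured members (0 and 13 adjusted over the list alone), with camera adjusted p = 1.36e-06. Stard4, a sterol carrier, averaged 40.02 ± 2.43 against 57.2 ± 2.89 CPM.

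Of the 12 measured tuft markers, 0 rose and 11 fell (0 and 12 adjusted over the list alone), with camera adjusted p = 1.32e-22. Of the 13 measured goblet markers, 1 rose and 9 fell (2 and 9 adjusted over the list alone), with camera adjusted p = 8.3e-12, or adjusted p = 0.0552 with an estimated correlation. Fcgbp, a mucus protein, averaged 42.8 ± 10.8 against 208 ± 3.34 CPM, while the goblet-like share did not pass its test at -0.36 (adjusted p = 0.102). Within that class, cluster 13 was 0.562% and 0.583% of control cells and held 0 of 1284 and 0 of 1412 cells with Rspo1, which allows shares of up to 0.234% and 0.212%. Of the 20 measured enterocyte markers, 17 rose and 2 fell (17 and 2 adjusted over the list alone), with camera adjusted p = 4.84e-35. Among Paneth markers, 9 of 14 measured members rose and 3 fell (9 and 3 adjusted over the list alone), with camera adjusted p = 0.891. Their median change was 0.71, their mean -0.25 and the direction of the test up, and the members that fell were the alpha-defensins Defa21, Defa3 and Defa22. Defa21 (ENSMUSG00000074447, chromosome 8, 21025545 to 21026516, plus strand) averaged 0.998 ± 0.185 against 49.3 ± 23.3 CPM and Defa3 (ENSMUSG00000074440, chromosome 8, 21287409 to 21288377, plus strand) 1.86 ± 0.234 against 52.3 ± 3.405 CPM, values that are uncertain because near-identical defensin copies share reads. Defa21 and Defa3 were among 9 genes that lay at least 2-fold apart between every library of the 3 gain-of-function groups and every library of the other 4 groups. Log2 ratios of shares were -0.24 (adjusted p = 0.0594) for ISC-like cells, 0.55 (adjusted p = 9.2e-05) for cycling cells with high stem markers, -3.56 (adjusted p = 6.09e-08) for those with low stem markers, 1.45 (adjusted p = 3.56e-05) for enterocyte-like and -1.88 (adjusted p = 0.000109) for tuft-like cells. The ISC-like ratio passed its test with a replicate block, at -0.24 (adjusted p = 0.00619), in a finer clustering, at -0.31 (adjusted p = 0.0109), and without library 2 of Rspo1, at -0.40 (adjusted p = 0.00059). With the cycling clusters of high stem markers included, an alternative chosen after the data were seen, its direction turned to 0.089 (adjusted p = 0.121). Out of 11754 genes tested, 1157 rose and 1280 fell, with 1389 by DESeq2, 400 against a minimum fold of 1.5 and 1624 without library 1 of the control.

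Within ISC-like cells, which came mostly from cluster 0 with Rspo1 and from cluster 2 in the control, interferon response and MHC class II genes rose. Lgr5, 82.1 ± 1.8 against 70.4 ± 0.989 CPM, and Ascl2, 261 ± 1.31 against 266 ± 17.3 CPM, did not pass, whereas Axin2 rose by 0.25 ± 0.07 (adjusted p = 0.0152). In these cells 25 of 26 measured interferon response genes rose and 0 fell (26 and 0 adjusted over the list alone), with camera adjusted p = 1.13e-37. Among MHC class II genes, 7 of 7 measured members rose and 0 fell (7 and 0 adjusted over the list alone), with camera adjusted p = 1.55e-44. Among Wnt targets, 8 of 21 measured members rose and 1 fell (9 and 1 adjusted over the list alone), with camera adjusted p = 0.000295, or adjusted p = 0.0709 with an estimated correlation. Mmp7, a matrix protease of Paneth cells, averaged 59.2 ± 5.05 against 6.77 ± 0.311 CPM and Reg3b 1387 ± 8.85 against 305 ± 122 CPM. Free RNA from other cells was not tested as the source of these rises. Over all cells Mmp7 was also higher, at 222.26 and 180.0 CPM with Rspo1 against 72.29 and 59.12 in the control. Ccl28, a mucosal chemokine, fell to 32.8 ± 2.69 against 141 ± 5.02 CPM. Of 10406 genes tested, 543 rose and 648 fell. DESeq2 called 464, a minimum fold of 1.5 left 152, leaving out library 2 of the control gave 715, and including cycling clusters with high stem markers 2123.

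RSPO2 addressed the same question with a second R-spondin. Stem and Wnt target genes rose, MHC class II and interferon response genes rose, and goblet, tuft and cholesterol synthesis genes fell. Lgr5 averaged 85.4 ± 2.18 against 49.03 ± 6.47 CPM, Ascl2 261 ± 6.26 against 219 ± 0.124 CPM and Axin2 207 ± 5.62 against 142 ± 2.23 CPM, changes of 0.76 ± 0.08 (adjusted p = 2.18e-07), 0.23 ± 0.06 (adjusted p = 0.00431) and 0.52 ± 0.06 (adjusted p = 1.14e-06). Olfm4 and Mki67 did not pass, at -0.15 and -0.10. Nkd1 gave the largest rule-named rise, 52.3 ± 6.06 against 7.68 ± 1.92 CPM. Of the 33 measured genes of the stem cell signature, 27 rose and 2 fell (27 and 2 adjusted over the list alone), with camera adjusted p = 3.76e-24. Of the 21 measured Wnt targets, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with camera adjusted p = 4.24e-14. Sp5 (ENSMUSG00000075304, chromosome 2, 70474923 to 70477729, plus strand) averaged 106 ± 9.54 against 63.8 ± 1.097 CPM. Among MHC class II genes, 7 of 7 measured members rose and 0 fell (7 and 0 adjusted over the list alone), with camera adjusted p = 2.43e-38. Interferon response genes had 22 rises and 0 falls among 26 measured members (24 and 0 adjusted over the list alone), with camera adjusted p = 2.1e-27. H2-Aa averaged 643 ± 2.605 against 244 ± 7.23 CPM and Irf7 227 ± 5.79 against 77.4 ± 1.91 CPM. Among cholesterol synthesis genes, 0 of 18 measured members rose and 12 fell (0 and 15 adjusted over the list alone), with camera adjusted p = 1.74e-10. Oxidative phosphorylation genes had 0 rises and 18 falls among 20 measured members (0 and 19 adjusted over the list alone), with camera adjusted p = 2.94e-10. Id1 and Id3, targets of BMP signalling, stood at -1.04 ± 0.05 and -0.92 ± 0.06.

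Among tuft markers, 0 of 12 measured members rose and 11 fell (0 and 11 adjusted over the list alone), with camera adjusted p = 1.98e-13, or adjusted p = 0.0725 with an estimated correlation. Among goblet markers, 0 of 13 measured members rose and 9 fell (1 and 9 adjusted over the list alone), with camera adjusted p = 2.62e-09, or adjusted p = 0.0717 with an estimated correlation. The goblet-like share did not pass its test, at -0.08 (adjusted p = 0.726), and its cluster 13 was 0.074% and 0 of 1200 cells (up to 0.25%) against 0.562% and 0.583%. For the Paneth markers the median change was 0.45, the mean -0.58 and the direction of the test down (camera adjusted p = 0.152). Defa21 averaged 0.649 ± 0.355 against 49.3 ± 23.3 CPM and Defa3 1.15 ± 0.222 against 52.3 ± 3.405 CPM, with the same uncertainty of shared reads, while Mmp7 averaged 176 ± 55.4 against 65.7 ± 9.31 CPM. Among fat oxidation genes, 9 of 14 measured members rose and 2 fell (9 and 3 adjusted over the list alone), with camera adjusted p = 5.01e-10. Defa21 and Defa3 lay again among the genes that separate the gain-of-function groups from the other 4 groups. Log2 ratios of shares were -0.13 (adjusted p = 0.3) for ISC-like cells, 0.50 (adjusted p = 0.000334) for cycling cells with high stem markers, -5.76 (adjusted p = 6.8e-09) for those with low stem markers, -1.04 (adjusted p = 0.00996) for tuft-like and -0.17 (adjusted p = 0.726) for enterocyte-like cells. The ISC-like ratio turned to 0.124 (adjusted p = 0.0661) with the cycling clusters of high stem markers included. Of 11754 genes tested, 1141 rose and 1345 fell, with 1367 by DESeq2, 333 against a minimum fold of 1.5 and 1600 without library 1 of RSPO2.

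In ISC-like cells, again mostly of cluster 0 with RSPO2 and of cluster 2 in the control, Lgr5 rose and Olfm4 fell. Lgr5 averaged 104 ± 1.66 against 70.4 ± 0.989 CPM, Axin2 193 ± 7.08 against 145 ± 8.66 CPM and Olfm4 111 ± 6.19 against 142 ± 15.2 CPM, changes of 0.51 ± 0.09 (adjusted p = 5.43e-05), 0.37 ± 0.07 (adjusted p = 0.00013) and -0.42 ± 0.09 (adjusted p = 0.000837). Nkd1 averaged 55.6 ± 4.28 against 9.15 ± 1.68 CPM. Among Wnt targets, 10 of 21 measured members rose and 0 fell (11 and 0 adjusted over the list alone), with camera adjusted p = 2.18e-07, or adjusted p = 0.0657 with an estimated correlation. Among interferon response genes, 21 of 26 measured members rose and 0 fell (23 and 0 adjusted over the list alone), with camera adjusted p = 1.32e-28. Prelp, a matrix proteoglycan, fell to 19.1 ± 2.96 against 69.1 ± 6.17 CPM. Of 10406 genes tested, 604 rose and 714 fell. DESeq2 called 481, a minimum fold of 1.5 left 134, leaving out library 2 of the control gave 640 and library 1 of RSPO2 798, and including cycling clusters with high stem markers 2119.

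The R-spondins were then compared with each other. RSPO2 cells held less RNA of enterocyte and antimicrobial genes than Rspo1 cells, while Lgr5, Ascl2, Axin2, Olfm4 and Mki67 did not pass the test. Lgr5, 85.4 ± 2.18 against 72.7 ± 1.64 CPM, Ascl2, 261 ± 6.26 against 245 ± 1.73 CPM, and Axin2, 207 ± 5.62 against 190.0 ± 6.93 CPM, had adjusted p = 0.072, 0.499 and 0.342, and Olfm4 and Mki67 0.659 and 0.0671. Of the 20 measured enterocyte markers, 0 rose and 18 fell (0 and 18 adjusted over the list alone), with camera adjusted p = 1.09e-94. Apoa1 averaged 137 ± 6.27 against 555 ± 26.7 CPM. Among antimicrobial genes, 0 of 11 measured members rose and 5 fell (0 and 9 adjusted over the list alone), with camera adjusted p = 2.7e-16. Reg3b averaged 315 ± 29.5 against 1283 ± 31.96 CPM. Mitochondrially encoded genes had 0 rises and 5 falls among 10 measured members (0 and 6 adjusted over the list alone), with camera adjusted p = 8.78e-05, or adjusted p = 0.219 with an estimated correlation. Nkd1, 52.3 ± 6.06 against 30.9 ± 0.727 CPM, was the Wnt target with the smallest adjusted p. Ccl28 and Slc1a5, an amino acid transporter, were higher with RSPO2, at 111 ± 0 against 31.4 ± 0.6 CPM and 57.8 ± 1.36 against 22.2 ± 0.701 CPM, and Erdr1 gave the largest rule-named rise, at 3.35 ± 0.14. The enterocyte-like share had a log2 ratio of -1.62 (adjusted p = 9.75e-06) and the ISC-like share 0.11 (adjusted p = 0.532), which passed without library 2 of Rspo1 at 0.26 (adjusted p = 0.0221) and turned to -0.028 (adjusted p = 0.802) without library 1. Among 11754 genes tested, 311 rose and 457 fell, with 335 by DESeq2, 134 against a minimum fold of 1.5, 446 without library 1 of Rspo1, and 421 and 405 without libraries 1 and 2 of RSPO2. Within ISC-like cells, mostly of cluster 0 in both groups, 146 genes rose and 216 fell of 10406, with Lgr5 at 0.32 ± 0.08 (adjusted p = 0.0183). That count was 84 by DESeq2, 35 against a minimum fold of 1.5, 198 without library 1 of Rspo1, 176 and 224 without libraries 1 and 2 of RSPO2, and 652 with the cycling clusters included.

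Wnt gain of function with scFv-DKK1c asked how a Wnt agonist acts on the reporter-positive cells. Enterocyte and fat oxidation genes rose, S phase, ribosome assembly and several stem genes fell, and Lgr5 and Axin2 did not pass the test. Lgr5 averaged 49.3 ± 1.63 against 49.03 ± 6.47 CPM and Axin2 142 ± 8.18 against 142 ± 2.23 CPM, at adjusted p = 0.917 and 0.896, whereas Ascl2, 154 ± 8.43 against 219 ± 0.124 CPM, and Olfm4, 58.4 ± 4.92 against 110.0 ± 23.5 CPM, fell. Of the 33 measured genes of the stem cell signature, 3 rose and 12 fell (3 and 12 adjusted over the list alone), with camera adjusted p = 0.0298, or adjusted p = 0.515 with an estimated correlation. Of the 20 measured enterocyte markers, 20 rose and 0 fell (20 and 0 adjusted over the list alone), with camera adjusted p = 1.07e-123. Apoa1 averaged 1826 ± 222 against 129 ± 1.79 CPM, Fabp1 (ENSMUSG00000054422, chromosome 6, 71199827 to 71205023, plus strand), a fatty acid binding protein, 2282 ± 225 against 189.9 ± 1.6 CPM, and Lct, the lactase gene, 124 ± 15.9 against 8.71 ± 3.79 CPM. Among fat oxidation genes, 12 of 14 measured members rose and 0 fell (13 and 0 adjusted over the list alone), with camera adjusted p = 7.69e-30. Creb3l3 averaged 108 ± 5.25 against 7.07 ± 0.733 CPM. Of the 34 measured S phase genes, 0 rose and 29 fell (0 and 30 adjusted over the list alone), with camera adjusted p = 1.09e-09, or adjusted p = 0.0707 with an estimated correlation. Pcna, the sliding clamp of DNA replication, averaged 79.5 ± 5.77 against 148 ± 12.2 CPM, while Mki67 did not pass at -0.09. Among ribosome assembly genes, 0 of 16 measured members rose and 13 fell (0 and 14 adjusted over the list alone), with camera adjusted p = 1.73e-05, or adjusted p = 0.115 with an estimated correlation. Among Wnt targets, 0 of 21 measured members rose and 8 fell (0 and 8 adjusted over the list alone), with camera adjusted p = 0.00235, or adjusted p = 0.0977 with an estimated correlation. Among cholesterol synthesis genes, 0 of 18 measured members rose and 11 fell (0 and 12 adjusted over the list alone), with camera adjusted p = 2.25e-05, or adjusted p = 0.0566 with an estimated correlation. Fdps averaged 37.2 ± 0.425 against 77.5 ± 1.56 CPM. Among interferon response genes, 15 of 26 measured members rose and 1 fell (16 and 1 adjusted over the list alone), with camera adjusted p = 1.85e-08. Immune cell markers had 9 rises and 0 falls among 12 measured members (10 and 0 adjusted over the list alone), with camera adjusted p = 0.00861, or adjusted p = 0.44 with an estimated correlation. The immune-like class held only 2 of 1092 and 5 of 880 cells with scFv-DKK1c. Mitochondrially encoded genes had 7 rises and 0 falls among 10 measured members (7 and 0 adjusted over the list alone), with camera adjusted p = 0.00402, or adjusted p = 0.328 with an estimated correlation.

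Among Paneth markers, 11 of 14 measured members rose and 3 fell (11 and 3 adjusted over the list alone), with camera adjusted p = 0.00484, or adjusted p = 0.47 with an estimated correlation. Lyz1 averaged 1181 ± 5.06 against 341 ± 52.6 CPM, whereas Defa21, 0.399 ± 0.058 against 49.3 ± 23.3 CPM, and Defa3, 1.503 ± 0.778 against 52.3 ± 3.405 CPM, fell, with the uncertainty of shared reads. Both defensins lay here too among the genes that separate the gain-of-function groups from the other 4 groups. Reg3a, an antimicrobial lectin, averaged 99.6 ± 0.494 against 11.1 ± 0.891 CPM. Paneth-like cells were 5.08% ± 0.591 against 2.002% ± 0.052, a log2 ratio of 1.34 (adjusted p = 0.00434), and enterocyte-like cells 18.8% ± 1.87 against 1.95% ± 0.017, at 3.27 (adjusted p = 8.39e-11). The ISC-like share was 34.6% ± 1.68, at -0.56 (adjusted p = 0.000483), or -0.32 (adjusted p = 0.000136) with the cycling clusters of high stem markers included, and cycling cells with high stem markers 29.2% ± 2.08, at 0.05 (adjusted p = 0.626). Of 11754 genes tested, 1707 rose and 2117 fell, with 2347 by DESeq2. Against a minimum fold of 1.5, 501 rose and 85 fell.

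Within ISC-like cells, mostly of cluster 2 in both groups, genes of fat handling rose while Lgr5, Axin2 and Mki67 did not pass. Fabp1 averaged 560.5 ± 15.2 against 17.7 ± 1.199 CPM, Creb3l3 44.4 ± 0.602 against 2.47 ± 0.481 CPM and Angptl4, an inhibitor of lipoprotein lipase, 42.3 ± 4.897 against 4.18 ± 2.04 CPM. Among fat oxidation genes, 9 of 14 measured members rose and 0 fell (10 and 0 adjusted over the list alone), with camera adjusted p = 1.92e-43. Among enterocyte markers, 11 of 15 measured members rose and 0 fell (11 and 0 adjusted over the list alone), with camera adjusted p = 2.07e-39. Enterocyte-like cells, a possible source of free RNA, were 18.8% of scFv-DKK1c cells against 1.95% in the control. Free RNA at the level of Apoa1 would account for 3.252% to 20.46% of the rise of Fabp1, Creb3l3 and Angptl4. It was not tested for the enterocyte markers as a list. Ascl2, 201 ± 11.7 against 266 ± 17.3 CPM, and Olfm4, 78.8 ± 3.19 against 142 ± 15.2 CPM, fell. Among S phase genes, 0 of 34 measured members rose and 11 fell (0 and 19 adjusted over the list alone), with camera adjusted p = 3.22e-08, or adjusted p = 0.0994 with an estimated correlation. Ceacam10, a cell adhesion protein, averaged 42.98 ± 15.5 against 193 ± 4.4 CPM. Lgr5 and Axin2 stood at 0.11 ± 0.11 (adjusted p = 0.589) and 0.18 ± 0.08 (adjusted p = 0.138), and Mki67 at -0.46 ± 0.22 (adjusted p = 0.175). Mki67 turned to 0.28 (adjusted p = 0.0123) when cycling clusters with high stem markers were included. Of 10406 genes tested, 646 rose and 755 fell. DESeq2 called 658, a minimum fold of 1.5 left 86, single libraries left out gave 844 to 1065, and the cycling clusters 2216.

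**Figure D3:**
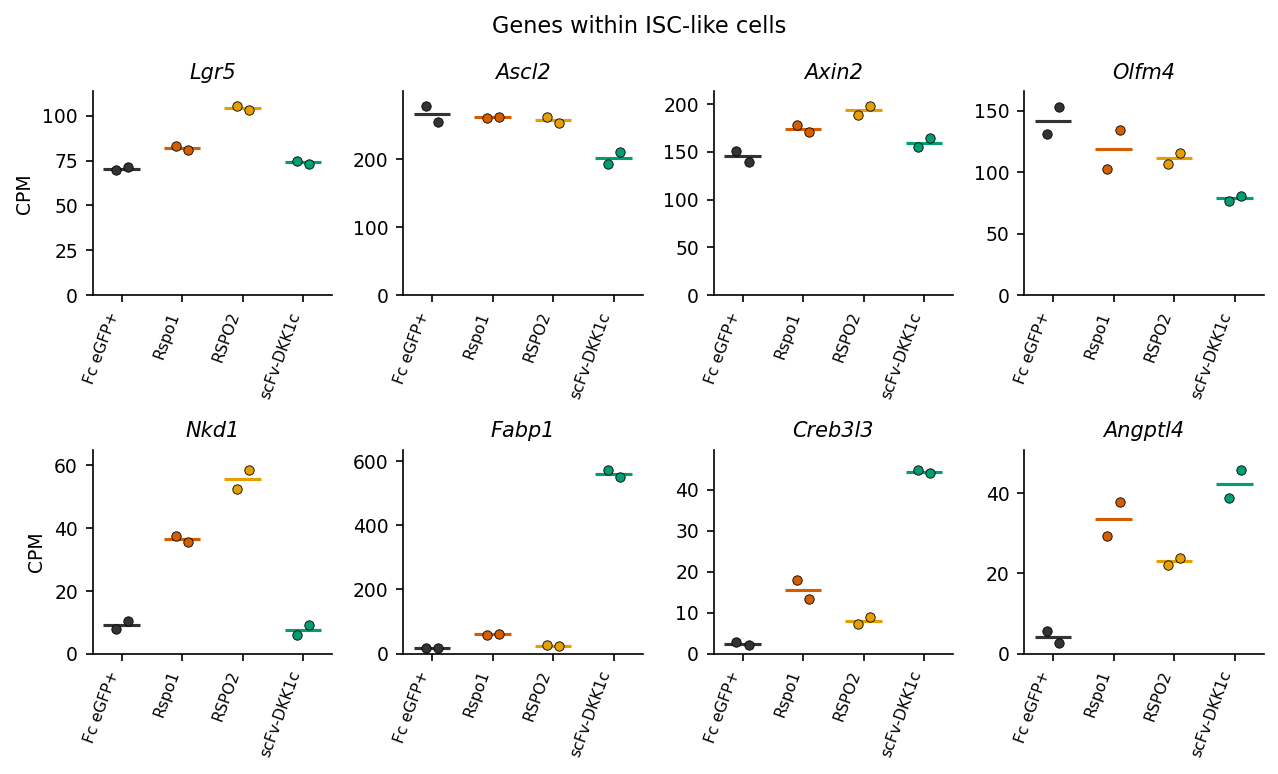
CPM within ISC-like cells (y axis) of 8 genes in the control and the 3 gain-of-function groups (x axis), with a dot per library and a line at the mean of the 2 libraries. Fabp1 averages 560.5 CPM with scFv-DKK1c against 17.7 in the control, and Nkd1 55.6 with RSPO2 against 9.15.

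A direct comparison of Rspo1 with scFv-DKK1c asked whether R-spondin and Wnt gain of function act alike. Stem, Wnt target, cell cycle and MHC class II genes were higher with Rspo1, and enterocyte, goblet, tuft and fat oxidation genes were lower. Lgr5 averaged 72.7 ± 1.64 against 49.3 ± 1.63 CPM, Ascl2 245 ± 1.73 against 154 ± 8.43 CPM, Axin2 190.0 ± 6.93 against 142 ± 8.18 CPM and Olfm4 108 ± 16.5 against 58.4 ± 4.92 CPM, at adjusted p = 6.17e-06, 3.12e-09, 5.93e-06 and 2.24e-06, and Mki67 stood at 0.20 ± 0.07 (adjusted p = 0.0255). Genes of the stem cell signature had 27 rises and 2 falls among 33 measured members (27 and 2 adjusted over the list alone), with camera adjusted p = 1e-13, or adjusted p = 0.0721 with an estimated correlation. Of the 21 measured Wnt targets, 17 rose and 0 fell (17 and 0 adjusted over the list alone), with camera adjusted p = 8.3e-14. Sp5, 101 ± 0.507 against 47.8 ± 4.197 CPM, and Cd44, a hyaluronan receptor, 101 ± 0.511 against 51.1 ± 3.22 CPM, were among them. Of the 34 measured S phase genes, 31 rose and 0 fell (32 and 0 adjusted over the list alone), with camera adjusted p = 4.21e-11, or adjusted p = 0.0566 with an estimated correlation. Of the 41 measured G2 and M phase genes, 33 rose and 0 fell (34 and 0 adjusted over the list alone), with camera adjusted p = 5.34e-10, or adjusted p = 0.119 with an estimated correlation. Cdk1, the mitotic kinase, averaged 146 ± 6.47 against 85.4 ± 4.12 CPM. MHC class II genes had 7 rises and 0 falls among 7 measured members (7 and 0 adjusted over the list alone), with camera adjusted p = 4.51e-14. Immune cell markers had 0 rises and 5 falls among 12 measured members (0 and 10 adjusted over the list alone), with camera adjusted p = 0.0221, or adjusted p = 0.491 with an estimated correlation. The immune-like class held only 1 to 5 cells per library in the groups compared. Among enterocyte markers, 0 of 20 measured members rose and 20 fell (0 and 20 adjusted over the list alone), with camera adjusted p = 7.38e-51. Fabp1 averaged 474 ± 23.8 against 2282 ± 225 CPM. Among fat oxidation genes, 0 of 14 measured members rose and 10 fell (0 and 11 adjusted over the list alone), with camera adjusted p = 3.33e-08. Among tuft markers, 0 of 12 measured members rose and 10 fell (0 and 10 adjusted over the list alone), with camera adjusted p = 1.03e-08, or adjusted p = 0.131 with an estimated correlation. Goblet markers had 0 rises and 10 falls among 13 measured members (0 and 10 adjusted over the list alone), with camera adjusted p = 8.35e-06, or adjusted p = 0.141 with an estimated correlation. Of the 9 measured genes of the regenerative program, 7 rose and 1 fell (7 and 2 adjusted over the list alone), with camera adjusted p = 0.000422, or adjusted p = 0.0509 with an estimated correlation. Ly6a averaged 36.5 ± 1.29 against 7.93 ± 2.09 CPM and Clu, a secreted chaperone, 18.7 ± 3.59 against 2.77 ± 1.64 CPM, whereas Anxa2, an annexin, was lower at -0.69.

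Log2 ratios of shares between Rspo1 and scFv-DKK1c were 0.32 (adjusted p = 0.0121) for ISC-like cells, 0.50 (adjusted p = 0.000272) for cycling cells with high stem markers, -1.82 (adjusted p = 4.95e-09) for enterocyte-like, -1.06 (adjusted p = 0.00562) for Paneth-like and -1.51 (adjusted p = 0.00126) for tuft-like cells. The ISC-like difference was not called without library 2 of Rspo1 (0.17, adjusted p = 0.0965) or library 1 of scFv-DKK1c (0.27, adjusted p = 0.098), in a finer clustering (0.23, adjusted p = 0.0513) or by limma on logit shares (0.51, adjusted p = 0.125). The test covered 11754 genes, of which 2310 rose and 2158 fell, with 2759 by DESeq2. Against a minimum fold of 1.5, 191 rose and 522 fell, and a fit of only the 4 libraries compared gave 2063 and 2350. Within ISC-like cells, mostly of cluster 0 with Rspo1 and cluster 2 with scFv-DKK1c, Lgr5 and Axin2 did not pass, at 0.09 and 0.07, whereas Ascl2 and Olfm4 were higher with Rspo1, at 0.32 and 0.55. Wnt targets had 10 rises and 0 falls among 21 measured members (13 and 0 adjusted over the list alone), with camera adjusted p = 5.32e-07. Interferon response genes had 20 rises and 0 falls among 26 measured members (21 and 0 adjusted over the list alone), with camera adjusted p = 1.71e-16. Fabp1 averaged 60.9 ± 2.96 against 560.5 ± 15.2 CPM and Reg3g, an antimicrobial lectin, 1029 ± 43.9 against 217 ± 22.4 CPM. For Reg3g, free RNA from other cells was not tested as the source. Of 10406 genes tested there, 837 rose and 858 fell, with 735 by DESeq2, 202 against a minimum fold of 1.5, 1083 to 1448 with single libraries left out and 2932 with the cycling clusters.

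**Figure D4:**
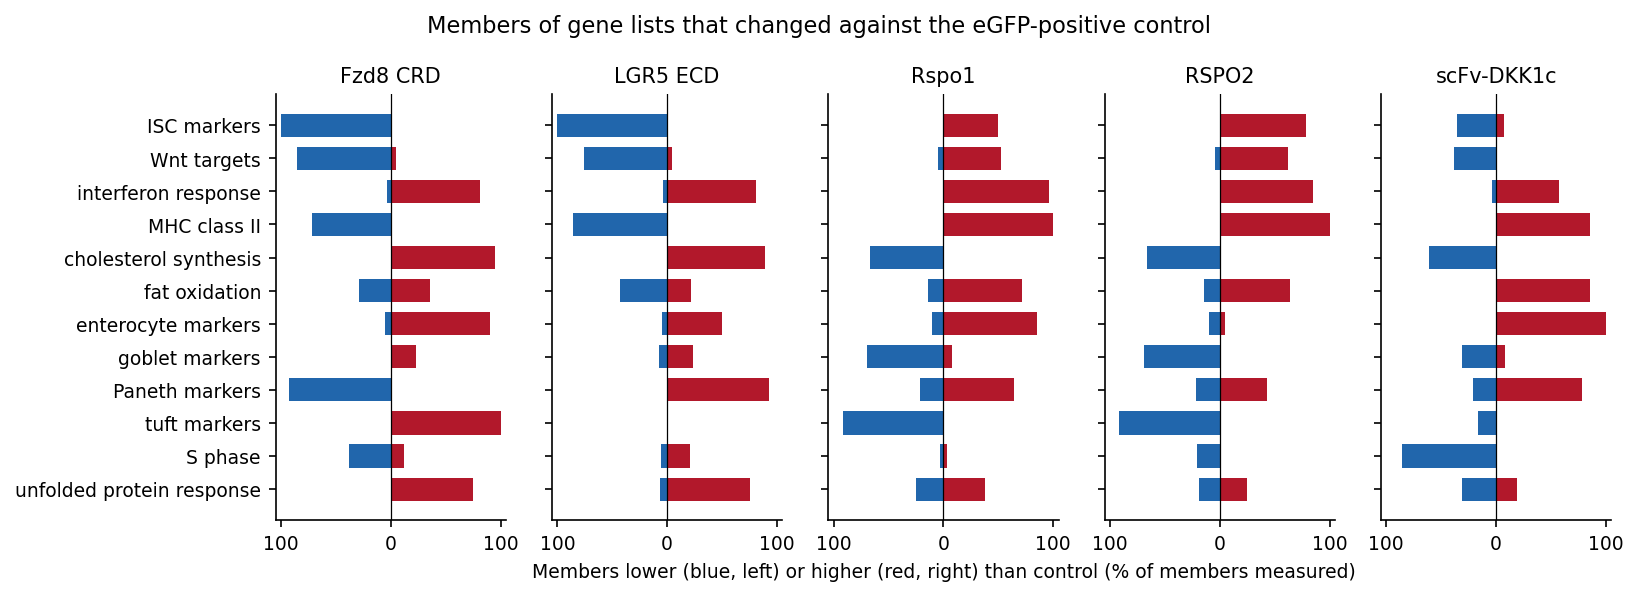
Percent of measured members of 12 gene lists that were lower (blue, left) or higher (red, right) than the eGFP-positive control in all cells (x axis), for the 5 treated groups (panels). Interferon response genes rise in each panel, from 15 of 26 with scFv-DKK1c to 25 of 26 with Rspo1, and Wnt targets fall with Fzd8 CRD and LGR5 ECD.

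**Figure D5:**
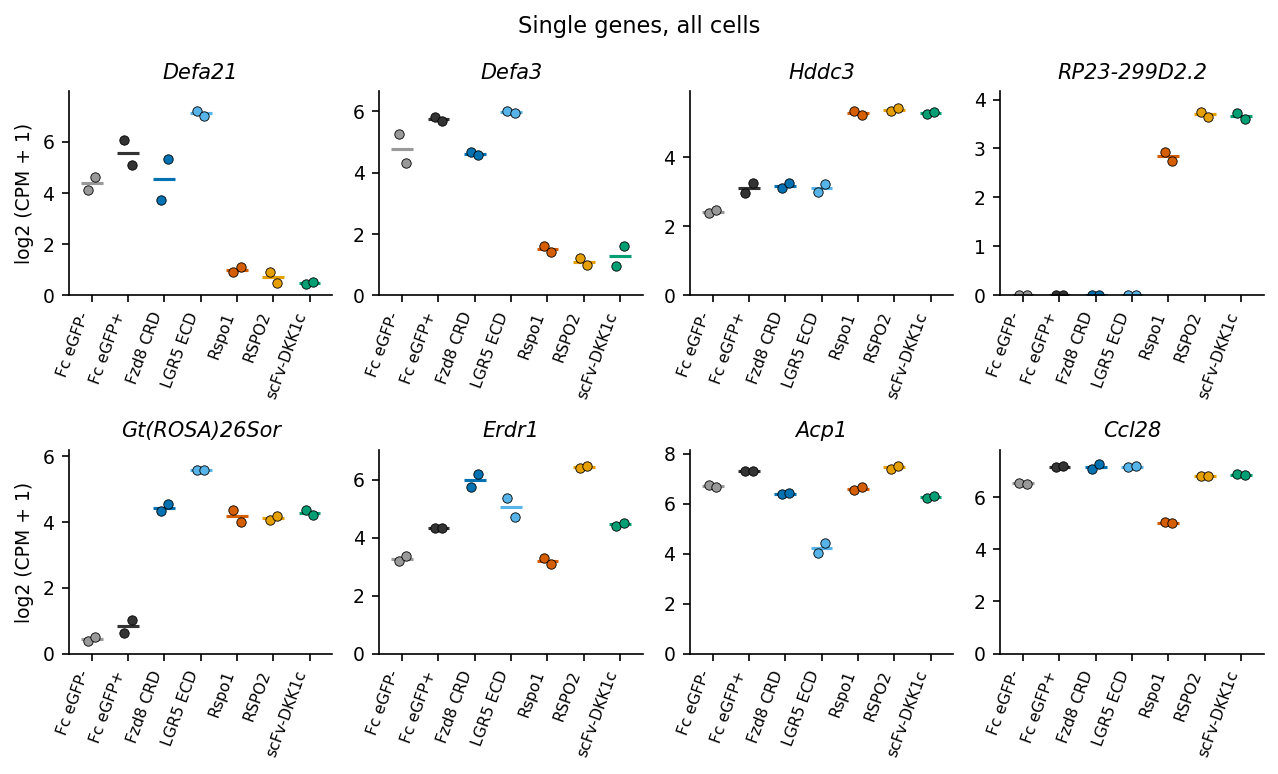
Log2 of CPM plus 1 over all kept cells (y axis) of 8 genes, most of them chosen after their values were seen, in the 7 groups (x axis), with a dot per library and a line at the mean of the 2 libraries. Defa21 and Defa3 lie between 0.40 and 1.86 CPM on average in the gain-of-function groups and at 20 CPM or more in the other 4 groups.

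As a check on depth, the share of cells with at least 1 Lgr5 UMI was taken after thinning every cell to 3600 UMIs, with exact binomial intervals kept per library. It was 16.9% ± 1.43 in eGFP-positive control cells, 1.40% ± 0.404 with Fzd8 CRD, 2.01% ± 0.507 with LGR5 ECD, 23.0% ± 0.601 with Rspo1, 26.6% ± 0.215 with RSPO2 and 16.6% ± 0.799 with scFv-DKK1c (SD, n = 2). Enterocyte-like cells, taken as a class without Lgr5, gave 0.535% as background at a median depth of 5249.5 UMIs, against median depths of 6639.5 to 8908 UMIs in the eGFP-positive libraries. That class was pooled over all 14 libraries, and most of its cells, 476 and 1012 before thinning, came from the eGFP-negative libraries. Those libraries averaged 1.08 CPM of Lgr5, so the background may be understated for eGFP-positive libraries. Without thinning the shares were 28.6%, 1.63%, 3.66%, 39.1%, 48.8% and 27.1% in the same order and 0.711% in enterocyte-like cells. The eGFP-negative control cells gave 0.364% ± 0.209 after thinning.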

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

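The 4 differences listed first come from comparisons fixed before the data were examined. The patterns weighed after them were chosen after the result was seen, as were all their tests except the one on the whole enterocyte-like class of control animals. Paneth-like cells were 2.886% and 4.0% with LGR5 ECD against 1.026% and 0.858% with Fzd8 CRD, on either side of 1.966% and 2.039% in the control, a log2 ratio of 1.91 (adjusted p = 0.0188). Neither share passed its edgeR test against the control (adjusted p = 0.106 for LGR5 ECD and 0.125 for Fzd8 CRD). Tuft-like cells were 1.698% and 1.733% against 5.641% and 5.489% in the same groups, with 2.247% and 2.427% in the control, a log2 ratio of -1.68 (adjusted p = 0.000224). Against the control only the Fzd8 CRD share passed, with adjusted p = 0.243 for LGR5 ECD. Ascl2 was 245.9 and 243.4 CPM with Rspo1 against 148.4 and 160.3 with scFv-DKK1c, around 219.2 and 219.0 in the control, a log2 ratio of 0.67 (adjusted p = 3.12e-09). Its change with Rspo1 did not pass against the control. Enterocyte-like cells were 1.636% and 1.833% with RSPO2 against 5.919% and 4.816% with Rspo1, and 1.966% and 1.942% in the control, a log2 ratio of -1.62 (adjusted p = 9.75e-06). The RSPO2 share did not pass against the control (adjusted p = 0.726).

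Defa21, Defa22 and Defa3 were lower with Rspo1, RSPO2 and scFv-DKK1c. Within Paneth-like cells their median log2 ratio was -6.14, with Defa22 less reduced, at 242.9, 184.2 and 154.6 CPM against 2604.6 in the control, whereas the log2 ratio of the Paneth-like share, which the sort also sets, was 0.1013 to 1.343 over the 3 groups, which argues against fewer Paneth cells as the whole cause. That test replaced one on other Paneth markers, by which the class is named. The lowest ratio, with RSPO2, came from 2 libraries at 3.123% and 1.083%, on either side of 1.966% and 2.039% in the control. Within Paneth-like cells, other defensin genes gained 199.9% to 357.5% of the lost CPM. Of these, AY761184 and Defa24 averaged 17956.5 and 30261.5 CPM with Rspo1 against 13652.7 and 25742.0 in the control. They reached 17858.6 and 30504.8 with LGR5 ECD, where Defa21, Defa22 and Defa3 kept 3484.6, 3309.6 and 1634.5 CPM, while Defa26 stood at 2969.5 against 2937.5. A gain without the loss cannot show where lost reads went, so reads moved between near-identical copies cannot be told apart from a real loss. Of 35 ways to divide 7 groups into 3 and 4, this one ranked 3 with 9 genes at least 2-fold apart in every library, Defa21 and Defa3 but not Defa22 among them, against a median of 0 and a highest other of 58. Another set of animals or another run in the 3 groups may also lie behind it, and the design confounds these with gain of function.

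Fabp1, Creb3l3 and Angptl4 were higher in ISC-like cells with scFv-DKK1c, at 560.47, 44.37 and 42.31 CPM against 17.7, 2.47 and 4.18 in the control. They averaged 60.94, 15.58 and 33.62 CPM with Rspo1 and 24.84, 8.1 and 22.97 with RSPO2. Free RNA at the level of Apoa1 would account for 3.252% to 20.46% of the rise, which argues against free RNA as the whole cause. The share of ISC-like cells with a UMI, unthinned, rose by 20.16 to 67.92 percentage points, which argues against rare doublets but says nothing of free RNA. That doublet test replaced a first version that could not decide. Within cluster 2 the median log2 rise kept 98.98% of its size, which argues against a different mix of clusters. A response to the Wnt agonist may lie behind it, but the genes were also above the control with both R-spondins, and another set of animals or another run in the 3 gain-of-function groups was not tested for these genes and stays open.

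Interferon response genes were higher than control in all 5 treated groups. Within cycling cells with low stem markers, a single cluster, the median rise kept 83.4% to 90.5% of its size in the loss-of-function groups, which argues against a changed mixture of classes there. With R-spondins it kept 108.7% to 119.7% within ISC-like cells, which were of different clusters, but 50.3% to 59.83% within cluster 0. That cluster held 8.287% and 9.903% of control cells against 37.072% to 45.083% of R-spondin cells, with the MHC class II gene H2-Eb1 among its top genes. It may thus hold the control cells most like treated ones, which would lower the rise. With scFv-DKK1c the median rise kept 57.13% within ISC-like cells. A mixture and a change within cells therefore cannot be told apart in these 3 groups. The tests were divided after these values were seen, and a test without immune-like cells was dropped since it moved nothing. Enterocyte-like cells of treated groups lay 0.9635 to 1.368 (log2) above those of control eGFP-negative libraries, which came from the other sort gate and mostly from clusters 4 and 8. Within cluster 6 alone, with 15 to 221 treated cells per group, they lay 0.3613 to 0.8396 above. Low values in the control animals may be the source, and they cannot be told apart from the encoded proteins.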

How the results depend on the processing

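The alternatives were fixed before the data were examined, except the addition of cycling clusters with high stem markers, and the replicate block and doublet removal for shares of other classes, which were chosen after the result was seen. The gene values counted in this paragraph are only those of genes named in the text, many of them chosen for a large change or a small adjusted p. Such genes were apt to keep their call, so these counts do not measure how stable the calls of all genes are. Of 321 gene values in all cells, 308 kept their direction and call with DESeq2, 321 with RLE scaling, 317 without a count filter, 320 without doublets, 320 with a replicate block, 321 with all barcodes and 230 against a 1.5-fold change. Immune-like cells removed left 316 of 321 and a fit of only the 4 libraries compared 317 of 320. With single libraries left out, 1243 of 1284 were kept, 38 lost their call, 2 gained one and 1 turned. In ISC-like cells, 52 of 56 were kept with DESeq2 and 213 of 224 with single libraries left out.

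Against a 1.5-fold change, 4923 genes passed for eGFP, 1072 for Fzd8 CRD, 495 for LGR5 ECD, 400 for Rspo1, 333 for RSPO2, 586 for scFv-DKK1c, 713 for Rspo1 against scFv-DKK1c, 232 for LGR5 ECD against Fzd8 CRD and 134 for RSPO2 against Rspo1. In ISC-like cells 152, 134, 86, 202 and 35 passed for Rspo1, RSPO2, scFv-DKK1c, Rspo1 against scFv-DKK1c and RSPO2 against Rspo1. This test calls fewer genes by construction. DESeq2 called 2532 genes for LGR5 ECD, 1389 for Rspo1, 1367 for RSPO2, 2347 for scFv-DKK1c, 2759 for Rspo1 against scFv-DKK1c, 668 for LGR5 ECD against Fzd8 CRD and 335 for RSPO2 against Rspo1, and in ISC-like cells 464, 481, 658, 735 and 84 in the order above, for which the cause was not tested. Cycling clusters included gave 2123, 2119, 2216, 2932 and 652, and Mki67 with scFv-DKK1c turned to 0.28 (adjusted p = 0.0123), a set that holds cycling cells by construction. Gzma with Fzd8 CRD, at 0 in the control, ranged from 0 to 10.1 with single libraries left out, and all of its counts lay in library 2 of Fzd8 CRD. With an estimated correlation, 53 of 270 list calls passed against 168.

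Without single libraries, where the lone library is assumed to vary like the other groups, counts ranged from 1624 to 1987 for Rspo1, 1600 to 1793 for RSPO2, 548 to 746 for LGR5 ECD against Fzd8 CRD and 405 to 559 for RSPO2 against Rspo1. In ISC-like cells they ranged from 715 to 921, 640 to 979, 844 to 1065, 1083 to 1448 and 176 to 278 in the order above. Fewer samples by construction lower these counts. The log2 ratio of the ISC-like share ranged from -0.40 to -0.11 for Rspo1, 0.17 to 0.46 for Rspo1 against scFv-DKK1c and -0.028 to 0.26 for RSPO2 against Rspo1. For Rspo1 it was -0.24 (adjusted p = 0.00619) with a replicate block and -0.31 (adjusted p = 0.0109) at Leiden resolution 2, and it turned to 0.089 (adjusted p = 0.121) with cycling clusters included, as did RSPO2 from -0.13 to 0.124 (adjusted p = 0.0661). The same alternative moved scFv-DKK1c from -0.56 to -0.32 (adjusted p = 0.000136) and turned LGR5 ECD against Fzd8 CRD from -0.08 to 0.69 (adjusted p = 0.274). The latter ranged from -0.40 to 0.18 with single libraries left out. For Rspo1 against scFv-DKK1c it was 0.51 (adjusted p = 0.125) with limma on logit shares and 0.23 (adjusted p = 0.0513) at resolution 2. For these shares the cause was not tested.

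Replicate numbers showed no pairing common to all groups. Over 21 pairs of groups, deviations from group means correlated between -0.174 and 0.2505, with 3 pairs over 0.1. These were RSPO2 with the eGFP-positive control at 0.2505, with Rspo1 at 0.1327 and with the eGFP-negative control at 0.1204. A pairing among those groups stays open. Depth limits shares of cells with a UMI, and 54 of 56 such values moved without thinning. Barcodes with at least 500 UMIs were not run apart from all barcodes, since none lay under that number. Genes in ISC-like cells of the loss-of-function groups had no value under any clustering, with under 20 cells per library.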

Other observations

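The results in this part were chosen after their values were seen, no explanation was tested for them, and group cannot be separated from animals or run. Antigen presentation genes moved in the remaining comparisons with the same control libraries too. With Fzd8 CRD, MHC class II genes had 0 rises and 5 falls among 7 measured members (0 and 5 adjusted over the list alone), with camera adjusted p = 0.00861, or adjusted p = 0.189 with an estimated correlation. With scFv-DKK1c, 6 of 7 measured MHC class II genes rose and 0 fell (6 and 0 adjusted over the list alone), with camera adjusted p = 0.00307, or adjusted p = 0.139 with an estimated correlation. In the same comparisons immune cell markers moved as well: 8 of 12 measured markers rose and 0 fell (10 and 0 adjusted over the list alone), with camera adjusted p = 0.0115, or adjusted p = 0.458 with an estimated correlation, for Fzd8 CRD, and 9 of 12 measured markers rose and 0 fell (10 and 0 adjusted over the list alone), with camera adjusted p = 0.00861, or adjusted p = 0.44 with an estimated correlation, for scFv-DKK1c. Immune-like cells were 0.172% ± 0.243 with Fzd8 CRD and 0.375% ± 0.272 with scFv-DKK1c, and 0 of 712 and 0 of 1030 in the control, which allows up to 0.421% and 0.291%. In cells these were 0 of 390 and 2 of 583 with Fzd8 CRD and 2 of 1092 and 5 of 880 with scFv-DKK1c. The marker rises may thus rest on few cells, and with Fzd8 CRD on 1 library.

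Some single genes differed in level between the treated groups. Values are CPM in eGFP-positive cells as mean ± SD (n = 2). Gt(ROSA)26Sor, the non-coding gene at the Rosa26 locus, was 0.8 ± 0.36 in the control, 20.6 ± 2.44 with Fzd8 CRD, 46.4 ± 0.44 with LGR5 ECD, 17.2 ± 3.46 with Rspo1, 16.2 ± 1.09 with RSPO2 and 18.4 ± 1.31 with scFv-DKK1c, and 0.36 ± 0.09 in eGFP-negative control cells. The labels give no genotype beyond the Lgr5 reporter. Erdr1, at the edge of the pseudoautosomal region, was 19.2 ± 0.08 in the control, 62.9 ± 13.5 with Fzd8 CRD, 32.9 ± 10.6 with LGR5 ECD, 8.25 ± 1.02 with Rspo1, 85.4 ± 2.95 with RSPO2 and 21.1 ± 1.23 with scFv-DKK1c. Acp1, a phosphatase, was 158 ± 1.64 in the control, 83.9 ± 2.69 with Fzd8 CRD, 18.03 ± 3.6 with LGR5 ECD, 96.4 ± 6.11 with Rspo1, 176 ± 10.3 with RSPO2 and 75.96 ± 2.92 with scFv-DKK1c.

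Ccl28, a chemokine of mucosal surfaces, was 142 ± 4.62 in the control, 142 ± 13.9 with Fzd8 CRD, 142 ± 1.07 with LGR5 ECD, 31.4 ± 0.6 with Rspo1, 111 ± 0 with RSPO2 and 115 ± 2.65 with scFv-DKK1c. Slc1a5, a glutamine transporter, was 54.9 ± 4.72 in the control, 14.2 ± 0.08 with Fzd8 CRD, 41.96 ± 4.46 with LGR5 ECD, 22.2 ± 0.7 with Rspo1, 57.9 ± 1.36 with RSPO2 and 74.5 ± 1.41 with scFv-DKK1c. RP23-299D2.2, an unnamed gene model, was listed at 0 in the control, Fzd8 CRD and LGR5 ECD groups and was 6.2 ± 0.64 with Rspo1, 11.98 ± 0.63 with RSPO2 and 11.7 ± 0.71 with scFv-DKK1c. Hddc3, a nucleotide hydrolase, was 7.69 ± 1.17 in the control, 8.07 ± 0.63 with Fzd8 CRD, 7.61 ± 0.93 with LGR5 ECD, 38.1 ± 2.4 with Rspo1, 40.6 ± 2.04 with RSPO2 and 37.9 ± 0.71 with scFv-DKK1c.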
